A study of Homo sapiens with 12 samples.

How the data were processed

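Gene expression was measured on Affymetrix 3′ expression arrays, on which each transcript is read by 1 or more probe sets, groups of short probes whose signals are combined into 1 level. Per the labels, the arrays were hybridised with biotinylated RNA amplified from 250 ng of total RNA of U937 cells, a human myeloid leukaemia line with monocytic features. The cells carried either a vector expressing EVI1 or the empty vector, and were treated for 24 h with 1 µM all-trans retinoic acid (ATRA) or with its solvent DMSO. The 12 arrays fall into 4 groups of 3 replicates: vector DMSO, vector ATRA, EVI1 DMSO and EVI1 ATRA. The series describes the replicates as biological.

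The deposited values are on the log2 scale. They were made with RMA (robust multi-array average, which corrects background, normalises between arrays and summarises each probe set) in Affymetrix Expression Console 1.3, per the submitters' processing notes, which give no settings. The table holds 54675 probe sets with 2 decimals. The medians of the 12 arrays lie between 5.29 and 5.35 and their lower quartiles between 3.83 and 3.91, so no further scaling was applied. All values that follow were computed from this table.

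The array annotation named 42898 of the probe sets and did not list 11777. Of the named probe sets, 1801 carried several gene symbols and were left out, and 41097 carried exactly 1 symbol. The Entrez identifiers of 41043 of these were found in the RefSeq gene table for assembly GRCh38.p14, and 0 symbols differed from it. That table was used only for names and for which genes are neighbours. The 41097 probe sets represent 19775 genes, 10523 of them with more than 1 probe set. Each gene was represented by its probe set with the highest mean over all arrays. Genes had to reach a log2 value of at least 5 on at least 3 arrays to be tested, which kept 14080 genes and removed 5695.

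Group means were fitted to all 12 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 8 residual degrees of freedom), and 5 comparisons were drawn from that fit. These were ATRA against DMSO in vector cells, ATRA against DMSO in EVI1 cells, EVI1 against vector under DMSO, EVI1 against vector under ATRA, and the interaction, which is the ATRA effect in EVI1 cells minus the ATRA effect in vector cells. Within each comparison, p-values were adjusted over all 14080 genes by the method of Benjamini and Hochberg. A gene was called at an adjusted p under 0.05, and called genes are described as risen or fallen. Differences are given as log2 differences with the standard error (SE) of the model, and group means with the standard deviation (SD) of 3 arrays. The number of arrays limits the precision of every value.

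The size of the ATRA response was compared between the cell types over genes with an adjusted p under 0.05 for the ATRA effect averaged over both cell types. The ATRA effect in each cell type was multiplied by the sign of the averaged effect and averaged over genes, and the difference was tested with limma's roast, a rotation test (2-sided, 9999 rotations). Over the same genes, the EVI1 effect averaged over both agents was measured along the direction of the ATRA response in the same way. In a balanced design neither value is favoured by the choice of genes. Overlaps of called genes were compared with the product of the counts over all genes by Fisher's exact test.

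A total of 29 gene lists was fixed, 23 for biology and 6 for markers of other cell types. The lists of biology cover retinoid signalling, monocyte and macrophage surface genes, granulocytic maturation, primary granules and immature myeloid genes, phagocyte NADPH oxidase, haematopoietic transcription factors, cell cycle, cell cycle arrest, apoptosis, interferon-stimulated genes, cytokines, MHC class II, MHC class I, integrins and adhesion, lysosome, lipid mediators, cholesterol synthesis, cholesterol efflux, glycolysis and hypoxia, unfolded protein and amino acid stress, heat shock, ribosome biogenesis with MYC targets, and genes linked to EVI1 in earlier work. The other lists cover erythroid, megakaryocyte, T and NK, B, epithelial, and fibroblast and endothelial markers. The apoptosis list holds regulators of cell death and was not split into promoters and inhibitors, so its direction does not say whether cell death was favoured. Each list was tested against the other genes with limma's camera at a preset correlation of 0.01, with adjustment over the 29 lists of a comparison. The test was repeated with the correlation between genes estimated from the arrays, and with fry (statmod 1.5.0), whose main p-value tests whether a list's genes move, on balance, in 1 direction, and whose mixed p-value tests for change in either direction. Neither p-value of fry compares a list with other genes. Members that the annotation did not name alone on a probe set, and members under the signal limit, were not tested.

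The genes named were chosen by a rule. In each comparison they were the 10 largest rises and the 10 largest falls among called genes whose arrays did not overlap between the 2 groups (5 of each for EVI1 against vector under ATRA; no separation of arrays was asked of the interaction). Whatever their values, 14 genes were named throughout: CYP26A1, DHRS3, RARB, RARA, TGM2, CD38, ITGAM, ITGAX, CEBPE, CD14, CYBB, MS4A3, MYC and GATA2. As examples of a list, up to 4 members with the smallest adjusted p were named. MECOM, the gene that encodes EVI1, was reported in all arrays first. Other genes that are named were chosen after their values were seen, and this is said where they appear. The grouping, the fit, the thresholds, the gene lists, the named-gene rule and most of the alternatives were chosen before the data were examined.

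The labels number the replicates from 1 to 3 in every group, and whether the numbers pair the arrays was checked on deviations from the group means. The 18 pairs of arrays with the same number in different groups correlated across genes with r from 0.408 to 0.704 (median 0.575). The 36 pairs with different numbers had r from -0.560 to 0.164 (median -0.336), and all 12 arrays correlated best with an array of their own number. The pairing comes from these values, since the labels do not say what a number shares. A fit with the replicate number as a block (6 residual degrees of freedom) lowered the median residual SD from 0.182 to 0.121 on the log2 scale. The fit without the block had been fixed as the reference, so blocked values are printed beside results whose call or count they change.

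The other alternatives were array weights, only the arrays compared, each gene by the median of its probe sets, every probe set on its own, no signal limit or a stricter one of 6.5, centring, cyclic loess, eBayes with trend and robust options, and leaving out each array in turn. The procedure was tested on simulated data with 14080 genes, in which 67 genes were changed by 0.5, 67 by 1 and 66 by 2 on the log2 scale. Replicate effects were simulated as equal in all groups, with independent noise of the size left by the blocked fit. The gain from the block is therefore built in, and false calls on the real arrays may differ. For ATRA against DMSO in vector cells, the fit without the block recovered 8.96%, 85.1% and 98.5% of these sizes with 1 false call, and the fit with the block recovered 70.1%, 100% and 100% with 9 false calls. For the interaction, the fit without the block recovered 0%, 47.8% and 97.0% with 0 false calls, and the fit with the block recovered 28.4%, 95.5% and 100% with 6 false calls.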

Results

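Transcript levels were measured in U937 cells to ask whether EVI1 alters how the transcriptome of a myeloid line reacts to ATRA. ATRA is a vitamin A derivative that activates retinoic acid receptors and drives maturation of some leukaemic cells. EVI1 is a zinc finger transcription factor encoded by MECOM and is an oncogene in myeloid leukaemia. The 4 groups, empty vector or EVI1 with DMSO or 1 µM ATRA for 24 h, held 3 arrays each. Between 13401 and 13774 of 19775 genes reached a log2 value of 5 on an array, and arrays of the same group correlated over all probe sets with r from 0.987 to 0.995. The first principal component of the tested genes held 52.0% of the variance and ran from the DMSO arrays (-35.3 to 1.8) to the ATRA arrays (-3.9 to 53.6). The second held 16.4% and was positive in all 6 EVI1 arrays and negative in all 6 vector arrays. The 3′ to 5′ difference of GAPDH probe sets, a measure of RNA integrity, was 0.15 to 0.32 on the 12 arrays, and that of ACTB was 0.34 to 0.70.

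MECOM, the transduced gene, was near the bottom of the signal range in all 12 arrays. Its 5 probe sets read 2.61 to 3.60 on the log2 scale, below the lower quartile of every array. The largest difference was 0.40 ± 0.15 (SE, n = 3) in EVI1 cells under ATRA, with a limma adjusted p of 0.211 over all probe sets (0.0705 with the replicate block). None of the 5 probe sets was called between EVI1 and vector cells under DMSO or under ATRA, with or without the block. The part of MECOM carried by the vector and the part read by the probe sets were not compared, so these arrays do not check the EVI1 label. Groups are named by their labels throughout.

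In vector cells, ATRA raised CD36, TGM2, THBD and CCR2 and lowered PTX3 and MYC. The scavenger receptor CD36 rose from 6.37 ± 0.58 to 10.18 ± 0.70 (SD, n = 3), a difference of 3.81 ± 0.72 (SE). TGM2, a transglutaminase induced by retinoids, rose from 5.15 ± 0.56 to 8.88 ± 1.10, and THBD, which encodes thrombomodulin, rose from 6.96 ± 1.16 to 10.12 ± 0.41. CCR2, a chemokine receptor of monocytes, rose by 3.34 ± 0.26 (SE), the smallest adjusted p among the 10 largest rises. PTX3, a secreted pentraxin, fell by 2.02 ± 0.26 (SE), and the transcription factor MYC fell from 12.44 ± 0.07 to 11.58 ± 0.10. In all, 496 genes passed the limma test in vector cells, 282 higher and 214 lower, against 2454 at an unadjusted p under 0.05 where 704 were expected by chance, and 145 of the called genes changed by at least 2-fold (108 higher, 37 lower). With the replicate block 2818 genes passed (1402 higher, 1416 lower), among them all 496 in the same direction. PTX3 in vector ATRA (3.97 to 4.02) was near the lower quartile of the arrays (3.83 to 3.91), where array signals compress fold differences. The adjusted p was 0.0178 for CD36, 0.0219 for TGM2, 0.00388 for THBD, 0.000357 for CCR2, 0.00295 for PTX3 and 0.0286 for MYC.

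The remaining large rises in vector cells were PALLD (3.66), NCF1 (3.27), PTGES (3.26), CD1D (3.23), ACKR3 (3.05) and PLAAT4 (2.96), with adjusted p from 0.0141 (PALLD) to 0.0413 (ACKR3). They encode the actin-associated palladin, an NADPH oxidase subunit, a prostaglandin E synthase, a lipid antigen presenting molecule, a chemokine scavenger and a retinoid-induced acyltransferase. ACKR3 read 4.10 in vector DMSO, with 1 array at or below the lower quartile of the arrays, so the size of its rise is limited by background. NCF1 has near-identical copies in the genome, so which copy its probe set reads is uncertain. PHACTR3 (-2.07), TENT5C (-2.02), CEP70 (-2.0), CCN3 (-1.93), SLC1A3 (-1.93), PLXNC1 (-1.76), TRIM71 (-1.72), CAB39L (-1.72) and SDCBP (-1.65) completed the 10 largest falls, with adjusted p from 0.0016 (PLXNC1) to 0.0384 (SDCBP). All of these genes moved in the same direction at all 3 replicate numbers. That is no further evidence, because the naming rule asks for arrays that do not overlap between the groups. ITGAM, which encodes the integrin chain CD11b, rose by 2.61 ± 0.57 (adjusted p = 0.0312).

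Several retinoid and maturation genes had large differences in vector cells that did not pass the limma test without the replicate block. DHRS3, a retinaldehyde reductase, differed by 3.68 ± 1.00 (adjusted p = 0.0714, blocked 0.00812), with an SD of 1.75 in vector DMSO. CD38 differed by 2.65 ± 0.72 (0.071, blocked 0.00823), the granulocytic transcription factor CEBPE by 0.99 ± 0.25 (0.0521, blocked 0.0106) and the retinoic acid receptor RARB by 0.86 ± 0.34 (0.202, blocked 0.00839). The DMSO arrays of number 3 stood nearer to the ATRA arrays. DHRS3 read 8.70 there in vector and 9.70 in EVI1 cells, against 5.30 to 6.30 on the other DMSO arrays, and CD38 read 9.34 and 9.45 against 6.44 to 7.05. Their scores along the ATRA response were -0.235 and -0.101, against -0.405 to -0.288 on the other DMSO arrays. ITGAX (0.86; 0.104, blocked 0.0044) and CYBB (1.60; 0.141, blocked 0.00139) passed only with the replicate block as well. The retinoic acid hydroxylase CYP26A1 (-0.14; 0.938), RARA (-0.26; 0.453), MS4A3 (-0.69; 0.525) and GATA2 (0.03; 0.933) passed neither fit. The monocyte marker CD14 was below the signal limit and was not tested, with means of 4.38 ± 0.39 in vector DMSO, 4.40 ± 0.07 in vector ATRA, 4.38 ± 0.21 in EVI1 DMSO and 4.46 ± 0.37 in EVI1 ATRA (SD, n = 3).

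**Figure D1:**
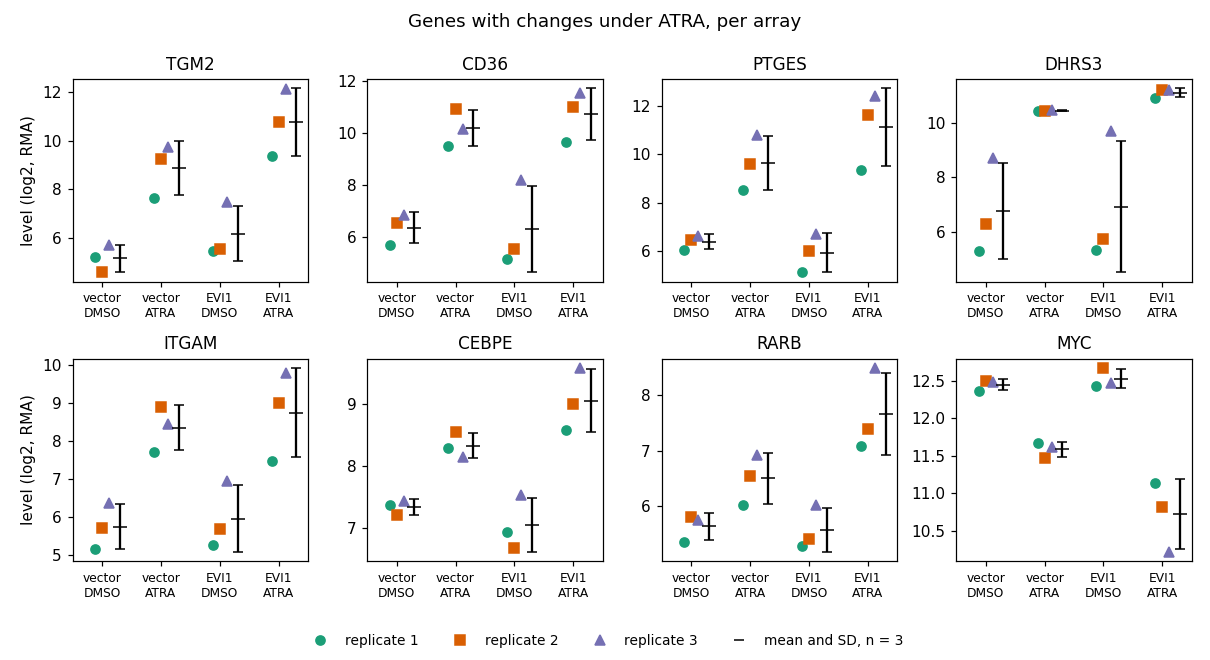
Levels (log2 RMA value, vertical axis) of 8 genes in the 4 groups (horizontal axis); points are arrays, with a colour and shape for each replicate number, and bars are the mean and SD (n = 3). PTGES rose from 6.37 to 9.64 in vector cells and from 5.92 to 11.14 in EVI1 cells, and MYC fell in both.

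Among gene groups in vector cells, interferon-stimulated and MHC class I genes had the smallest camera p-values of the lists that ran higher. Of 33 interferon-stimulated genes tested, 7 rose and none fell over all genes (14 rose adjusted over the list alone, 19 rose with the block), with a list median of 0.66. They included the transcription factors IRF1 (1.71) and IRF7 (1.06), the antiviral synthetase OAS3 (1.15) and IFI35 (0.72). Of 14 MHC class I genes, the immunoproteasome subunits PSMB9 (1.31) and PSMB10 (0.81) rose (10 rose adjusted over the list alone, 12 with the block). Among 17 genes of ribosome biogenesis and MYC targets all 17 differences were negative, with a median of -0.39, though only MYC passed the test over all genes (2 fell adjusted over the list alone, 12 with the block). The camera adjusted p was 1.31e-08 for the interferon list, 4.26e-07 for MHC class I and 7.37e-07 for ribosome biogenesis, and adjusted p = 0.397 with an estimated correlation for each.

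Maturation and effector lists also ran higher under ATRA in vector cells. Of 19 granulocytic genes 2 rose, ITGAM and the chemokine receptor CXCR2 (0.80), while 10 rose adjusted over the list alone and 9 rose with 1 falling with the block (camera adjusted p = 0.000142). Of 7 lipid mediator genes 3 rose in each count, PTGES, PTGS1 (1.68) and ALOX5AP (1.47; camera adjusted p = 0.00265). Of 21 lysosome genes 2 rose, NPC2 (0.73) and HEXA (0.75), and 9 rose adjusted over the list alone (camera adjusted p = 0.00201; 10 rose and 1 fell with the block). Of 23 integrin and adhesion genes 3 rose, ITGAL (1.92), ITGB7 (1.15) and ICAM3 (0.68), and CD47 fell (-0.79); 7 rose and 1 fell adjusted over the list alone, and 11 rose and 2 fell with the block (camera adjusted p = 0.0118). Of 10 NADPH oxidase genes 2 rose, NCF1 and CYBA (0.53), with 4 up and 1 down adjusted over the list alone and 5 up and 1 down with the block (camera adjusted p = 0.0386). These 5 lists each had adjusted p = 0.397 with an estimated correlation. Of 13 monocyte surface genes CD36 rose, and 3 did adjusted over the list alone and with the block (camera adjusted p = 0.0118; adjusted p = 0.455 with an estimated correlation). All 10 heat shock genes had negative differences with a median of -0.20, and limma called 0 of them over all genes or adjusted over the list alone (3 at an unadjusted p under 0.05, 3 with the block; camera adjusted p = 0.0118; adjusted p = 0.486 with an estimated correlation). The unfolded protein list moved down only with the block (camera adjusted p = 0.0591, blocked 0.023), although its member DDIT4 rose by 2.09, and MHC class II moved up only with the block (0.132, blocked 0.0436). With the block and an estimated correlation both had an adjusted p of 0.393.

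In EVI1 cells, ATRA raised many of the same genes, and the prostaglandin synthase PTGES rose most. PTGES rose from 5.92 ± 0.80 to 11.14 ± 1.61 (SD, n = 3), which is 37.4-fold, and TGM2 rose from 6.16 ± 1.14 to 10.77 ± 1.40. The granulocytic factor CEBPE rose by 2.00 ± 0.25 (SE), from 7.05 ± 0.44 to 9.05 ± 0.50 (SD), and RARB rose by 2.08 ± 0.34 (SE), from 5.57 ± 0.39 to 7.66 ± 0.74 (SD). MYC fell by 1.80 ± 0.18 (SE), from 12.52 ± 0.13 to 10.72 ± 0.46, and PTX3 fell from 6.08 ± 0.64 to 3.13 ± 0.28, which is below the lower quartile of the arrays, so the size of its fall is limited by background. In EVI1 cells 2127 genes passed the limma test, 1049 higher and 1078 lower, against 4056 at an unadjusted p under 0.05, and 443 of them changed by at least 2-fold (329 higher, 114 lower). With the replicate block 5023 passed (2298 higher, 2725 lower), among them all 2127 in the same direction. The adjusted p was 0.00145 for PTGES, 0.00268 for TGM2, 0.000998 for CEBPE, 0.00282 for RARB, 0.000465 for MYC and 0.000305 for PTX3.

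The other large rises in EVI1 cells were LILRA5 (4.69), CD36 (4.41), DHRS3 (4.18), PALLD (4.12), ACKR3 (4.10), SCN4B (3.89), KCNE1 (3.70) and HNRNPLL (3.68), with adjusted p from 0.000977 (SCN4B) to 0.0251 (HNRNPLL). SCN4B read 4.39 in EVI1 DMSO, with 1 array at or below the lower quartile of the arrays, so the size of its rise is limited by background. LILRA5 is a leukocyte immunoglobulin-like receptor, SCN4B and KCNE1 are ion channel subunits, and HNRNPLL regulates splicing in leukocytes. The other large falls were HS3ST2 (-2.47), SLC1A3 (-2.36), S1PR3 (-2.28), NOG (-2.24), CCN3 (-2.07), POLR3G (-2.04), TENT5C (-1.93) and PHACTR3 (-1.81), with adjusted p from 0.000103 (HS3ST2) to 0.0133 (TENT5C). HS3ST2 modifies heparan sulfate, SLC1A3 transports glutamate, S1PR3 binds sphingosine 1-phosphate and NOG antagonises bone morphogenetic proteins. All of these genes, and MYC, moved in the same direction at all 3 replicate numbers, as genes must whose arrays do not overlap between the groups. CD38 (3.14; adjusted p = 0.014), ITGAM (2.80; 0.00859), CYBB (1.78; 0.0461) and ITGAX (1.07; 0.018) also rose. CYP26A1 differed by 1.39 ± 0.52 (0.0939, blocked 0.0416), with an SD of 1.51 in EVI1 ATRA, and MS4A3 by -1.0 (0.199, blocked 0.014). RARA (0.41; 0.104) and GATA2 (-0.03; 0.897) passed neither fit.

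Lists of proliferation genes ran lower with ATRA in EVI1 cells by camera at the preset correlation. All 17 ribosome biogenesis and MYC target genes had negative differences with a median of -0.74, and 13 fell, among them the RNA polymerase subunit POLR1B (-0.92), the pyrimidine synthesis enzyme CAD (-0.99) and WDR12 (-0.81). Adjusted over the list alone 15 fell, and 16 with the block. All 36 cell cycle genes were negative with a median of -0.38, and 6 fell, among them the replication factors MCM2 (-0.79), MCM4 (-0.66), MCM6 (-0.56) and CDC45 (-0.97). Adjusted over the list alone 13 cell cycle genes fell, and 21 with the block. The camera adjusted p was 1.85e-09 for ribosome biogenesis (adjusted p = 0.241 with an estimated correlation) and 7.96e-06 for the cell cycle (adjusted p = 0.518 with an estimated correlation). Heat shock genes moved down only with the block (camera adjusted p = 0.0546, blocked 0.0187, and 0.28 with the block and an estimated correlation). In that list HSPE1 (-0.42) and HSP90AB1 (-0.36) fell over all genes, 3 fell adjusted over the list alone and 6 with the block.

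Interferon, maturation and effector lists ran higher with ATRA in EVI1 cells by camera at the preset correlation. Of 33 interferon-stimulated genes 15 rose, including IRF9 (1.65), OAS3 (1.32), IRF7 (1.26) and IFI35 (1.05), with 16 up and 1 down adjusted over the list alone and 24 up and 2 down with the block (camera adjusted p = 1.09e-08; adjusted p = 0.261 with an estimated correlation). Of 19 granulocytic genes 9 rose, including CEBPE, the formyl peptide receptor FPR2 (1.43), the growth factor receptor CSF3R (1.32) and CXCR2 (1.11), and 10 rose adjusted over the list alone (camera adjusted p = 2.43e-05). Of 13 monocyte surface genes 6 rose over all genes and adjusted over the list alone, among them CD300LF (0.55) and LILRB1 (0.64; camera adjusted p = 0.00116). Of 10 NADPH oxidase genes 5 rose, with NCF1 (3.53), CYBB, CYBA (0.52) and RAC2 (0.37), and 6 adjusted over the list alone (camera adjusted p = 0.00269). Of 7 lipid mediator genes 4 rose in both counts, PTGES, PTGS1 (2.09), ALOX5AP (1.41) and TBXAS1 (0.69; camera adjusted p = 0.000411). Of 21 lysosome genes 9 rose, and 11 adjusted over the list alone (camera adjusted p = 0.00173). Each of these 5 lists had adjusted p = 0.241 with an estimated correlation.

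The remaining called lists in EVI1 cells held members that went both ways. Of 24 apoptosis genes 9 rose, among them DAPK1 (1.46), CASP8 (0.70) and CASP1 (0.59), and the death receptor TNFRSF10B fell (-0.66); adjusted over the list alone 12 rose and 2 fell (camera adjusted p = 0.0011). Of 14 MHC class I genes 4 rose, including PSMB10 (0.74), TAPBP (0.54) and NLRC5 (0.38), and TAP2 fell (-0.32), with 8 up and 1 down adjusted over the list alone and 11 up and 1 down with the block (camera adjusted p = 0.000424). Of 23 integrin and adhesion genes 7 rose, including ITGAL (2.34), ITGB7 (1.51), ICAM1 (1.13) and PECAM1 (1.10), and 2 fell, with 9 up and 2 down adjusted over the list alone (camera adjusted p = 0.00452). Each of these 3 lists had adjusted p = 0.241 with an estimated correlation. The retinoid list itself was not called (camera adjusted p = 0.0742), with TGM2, RARB, DHRS3 and the repressor HIC1 (3.03) up and the retinol dehydrogenase RDH10 down (-0.75), which is 4 up and 1 down over all genes and adjusted over the list alone, and 7 up and 2 down with the block.

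The genes that responded to ATRA were largely shared between the cell types. Of the 496 genes called in vector cells, 436 were called in the same direction in EVI1 cells, 246 higher and 190 lower, where 21 and 16.4 were expected from the counts, and none was called in opposite directions. CD36, TGM2, PTGES, PALLD and ACKR3 were among the 10 largest rises of both cell types, and PTX3, PHACTR3, TENT5C, CCN3 and SLC1A3 were among the 10 largest falls of both. Fisher's exact p was 3.98e-246 for the higher and 4.9e-189 for the lower genes, with the reservation that genes are not independent replicates. Across the 14080 genes, which are not independent replicates either, ATRA effects correlated with r = 0.847 and rho = 0.716. With the block 2341 genes were shared in direction, and 4 were called in opposite directions.

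**Figure D2:**
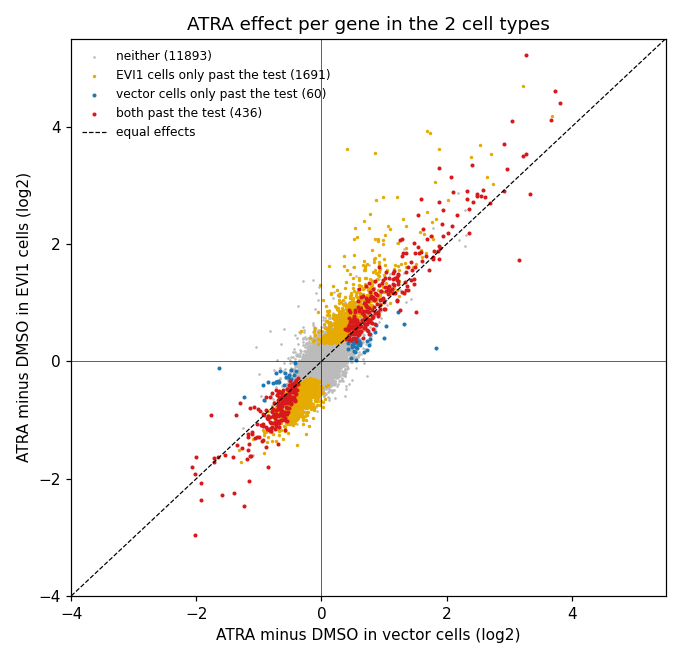
ATRA effect of each of 14080 genes (points) in vector cells (horizontal axis, log2) and in EVI1 cells (vertical axis, log2); colours mark genes called in both (436), in EVI1 cells alone (1691), in vector cells alone (60) or in neither (11893), and the dashed line marks equal effects. Over all genes the effects on the 2 axes correlate with r = 0.847, and no gene is called in opposite directions.

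Several response genes had larger ATRA effects in EVI1 cells, but no single gene passed a test of that difference. RARB had an ATRA effect larger by 1.22 ± 0.48 (SE, n = 3 per group) in EVI1 cells, CEBPE by 1.01 ± 0.35 and TGM2 by 0.88 ± 1.04. MYC had an effect more negative by -0.94 ± 0.26. The difference was also positive for RARA (0.67 ± 0.22) and CYP26A1 (1.53 ± 0.73). Each of these 6 differences had the same direction at all 3 replicate numbers. RARA was called in neither cell type, and its ATRA differences there had opposite signs. CYP26A1 was not called in vector cells, and in EVI1 cells it was called only with the block. CCR2, PLXNC1 and CADM1, chosen after their values were seen, had smaller ATRA effects in EVI1 cells. Without EVI1 ATRA array 3, the difference was 0.80 for RARB, 0.66 for CYP26A1 and 0.19 for TGM2. For TGM2 it was also 0.26 without vector ATRA array 1, 0.53, 0.57 and 1.54 without EVI1 DMSO arrays 1, 2 and 3, and 1.58 without EVI1 ATRA array 1. DHRS3 (0.50), CD38 (0.49), ITGAX (0.21), ITGAM (0.18), CYBB (0.18), GATA2 (-0.06) and MS4A3 (-0.30) differed less. The limma interaction test called 0 genes (adjusted p = 0.998 for every gene named here), with 362 genes at an unadjusted p under 0.05 against 704 expected by chance. With the block it also called 0, with 1846 unadjusted, and the smallest adjusted p was 0.346, shared by RARB, CEBPE, RARA and MYC. Differences between replicate numbers stay in the residual SD of the fit without the block (median 0.182, against 0.121 with it). The count of 362, below the number expected by chance, is therefore no evidence that ATRA effects were equal. Array weights called 1 gene, as did leaving out EVI1 ATRA array 1: DDC, which encodes DOPA decarboxylase, at -1.16 (adjusted p = 0.0391) and -1.19 (adjusted p = 0.0227); it is named after its values were seen.

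Averaged over all responding genes, the ATRA effect was larger in EVI1 cells, and whether it passed the test depended on the replicate block. Over 3158 genes, such as PTGES and MYC, chosen by the effect averaged over both cell types (1568 of them higher), the mean response was 0.491 in vector cells and 0.685 in EVI1 cells, a ratio of 1.39, and 80.7% of the genes differed in that direction. The difference was 0.193 (limma roast p of 0.188), and it was 0.138, 0.175 and 0.268 for replicate numbers 1, 2 and 3. An exact permutation of the signs of these 3 differences gave p = 0.25, the smallest value that 3 pairs can give. With the block the genes chosen numbered 5723, the means were 0.368 and 0.524, and the difference was 0.156 (limma roast p of 0.0332). Split by direction, the blocked difference was 0.157 for 2705 genes higher under ATRA (limma roast p of 0.145) and 0.155 for 3018 lower genes (0.0293), and it was 0.450 for 322 genes of at least 2-fold (0.0917). Without EVI1 ATRA array 1 the difference was 0.325 (limma roast p of 0.0393), without EVI1 ATRA array 3 it was 0.121 (0.314), and without vector DMSO array 3 it was 0.122 (0.446). The EVI1 effect averaged over both agents ran along the ATRA response by 0.167 (limma roast p of 0.0364; 12 of 200 splits in an exact permutation of the cell-type labels within each agent), with 76.4% of genes in that direction. At each replicate number it was larger under ATRA (0.155, 0.235, 0.401) than under DMSO (0.0168, 0.0606, 0.134), which is the size difference above in another form. That test was no longer passed without vector ATRA array 1, vector DMSO array 2, EVI1 DMSO array 2, EVI1 DMSO array 3 or EVI1 ATRA array 3 (limma roast; lowest value 0.129, largest p 0.134). With the block the effect was 0.137 (limma roast p of 0.0022), without EVI1 ATRA array 3 it was 0.122 (0.0051), and for genes of at least 2-fold it was 0.385 (0.0115).

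The gene groups with the clearest difference in ATRA response were those of proliferation. ATRA effects were more negative in EVI1 cells for 35 of 36 cell cycle genes (median difference -0.38) and for 16 of 17 ribosome biogenesis and MYC target genes (median -0.37), including MYC. They were more positive for 20 of 24 apoptosis regulators (median 0.15) and 13 of 19 granulocytic genes (median 0.17), including CEBPE. The limma test called 0 members of these 4 lists over all genes, with or without the block, and 0 adjusted over the list alone, and 1 cell cycle, 1 ribosome biogenesis, 1 granulocytic and 0 apoptosis genes had an unadjusted p under 0.05. With the block, 2 cell cycle and 11 ribosome biogenesis genes were called as more negative when adjusted over the list alone. The camera adjusted p was 3.16e-10 for the cell cycle, 8e-06 for ribosome biogenesis, 0.001 for apoptosis and 0.0297 for granulocytic genes, and each had adjusted p = 0.469 with an estimated correlation. The smallest fry adjusted p of any list was 0.708. With the block, interferon-stimulated genes (camera adjusted p = 0.063, blocked 0.0234), lipid mediators (0.063, blocked 0.047) and fibroblast and endothelial markers (0.0612, blocked 0.047) were also called as more positive. With the block and an estimated correlation each of these 3 had an adjusted p of 0.557. In the glycolysis list, PFKFB3, a regulator of glycolysis, differed by 0.71 and passed when adjusted over the list alone (0.0244).

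**Figure D3:**
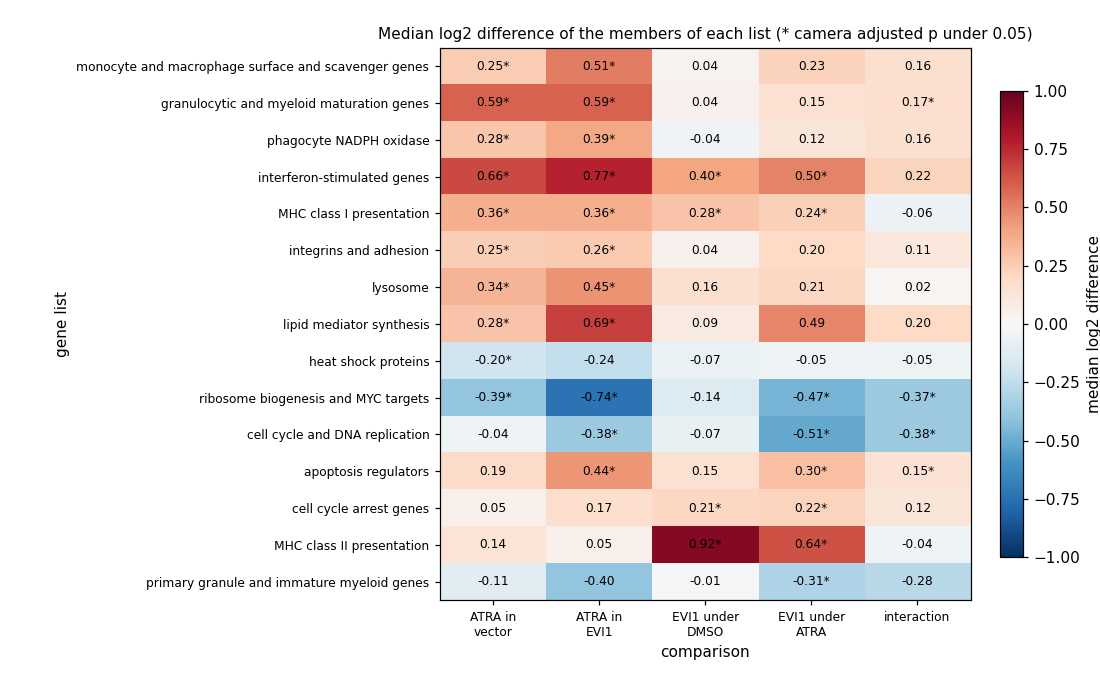
Median log2 difference (colour, from -1 to 1) of 15 gene lists (vertical axis) in the 5 comparisons (horizontal axis), with an asterisk where the camera adjusted p was under 0.05 at the preset correlation. Cell cycle genes had a median of -0.38 for ATRA in EVI1 cells and again for the interaction, and interferon-stimulated genes were called in every comparison but the interaction. With an estimated correlation no list was called in any comparison.

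Without ATRA, EVI1 and vector cells differed most in a few transcripts that fell to near the lower quartile of the arrays in EVI1 cells. DNAJC15, which encodes a mitochondrial co-chaperone, fell from 9.35 ± 0.05 to 4.30 ± 0.33 (SD, n = 3). The long non-coding RNA LINC01088 fell from 8.30 ± 0.51 to 3.56 ± 0.46, the lysosomal membrane protein gene TMEM106B from 8.17 ± 0.35 to 3.86 ± 0.58, and THBD from 6.96 ± 1.16 to 3.52 ± 0.19. ASH2L, a subunit of histone methyltransferase complexes, fell from 12.15 ± 0.10 to 9.87 ± 0.08, which is 4.87-fold. HS3ST2 rose from 6.92 ± 0.20 to 8.85 ± 0.16, and CDKN1A, which encodes the cell cycle inhibitor p21, rose from 7.85 ± 0.27 to 9.15 ± 0.51. Under DMSO 171 genes passed the limma test, 75 higher and 96 lower in EVI1 cells, against 1379 at an unadjusted p under 0.05, and 45 of them differed by at least 2-fold (14 higher, 31 lower). With the block 1013 passed (592 higher, 421 lower), among them all 171 in the same direction. The adjusted p was 5.69e-08 for DNAJC15 (-5.05 ± 0.18), 1.47e-05 for LINC01088 (-4.74 ± 0.33), 5.72e-05 for TMEM106B (-4.31 ± 0.34), 0.00226 for THBD (-3.44 ± 0.43), 2.98e-07 for ASH2L (-2.28 ± 0.10), 0.000162 for HS3ST2 (1.93 ± 0.17) and 0.02 for CDKN1A (1.3 ± 0.24).

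CLGN (-3.05), LTBP1 (-2.69), NFE2L3 (-1.94), NEO1 (-1.91) and STAR (-1.88) completed the 10 largest falls in EVI1 cells under DMSO, with adjusted p from 7.77e-06 (LTBP1) to 0.0011 (NFE2L3). They encode a chaperone of the endoplasmic reticulum, a binding protein of latent TGF-beta, a transcription factor, a netrin receptor and a mitochondrial cholesterol transporter. In EVI1 cells, DNAJC15, LINC01088, TMEM106B, THBD and CLGN were near the lower quartile of the arrays (3.83 to 3.91), where array signals compress fold differences. LMNB1 (1.74), DOCK9 (1.69), FRMD4A (1.56), SASH1 (1.40), GPR18 (1.39), TRIM71 (1.32), ATP9A (1.31) and TXNDC2 (1.27) completed the largest rises, with adjusted p from 0.00098 (GPR18) to 0.0195 (TXNDC2). LMNB1 encodes a nuclear lamin and DOCK9 a guanine nucleotide exchange factor. All 20 genes moved in the same direction at all 3 replicate numbers. The naming rule fixes this in advance, since it asks for arrays that do not overlap between the groups. ASH2L and STAR lie close together on chromosome 8, where 17 of 18 further neighbouring genes were also lower in EVI1 cells. Of the 10 tested genes nearest to THBD on chromosome 20, 3 were below -0.5. Of the genes named in every comparison none passed the test under DMSO; MS4A3, a marker of granulocyte and monocyte progenitors, differed by -1.75 ± 0.48 (adjusted p = 0.128, blocked 0.00345), and TGM2 by 1.01 (0.799).

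**Figure D4:**
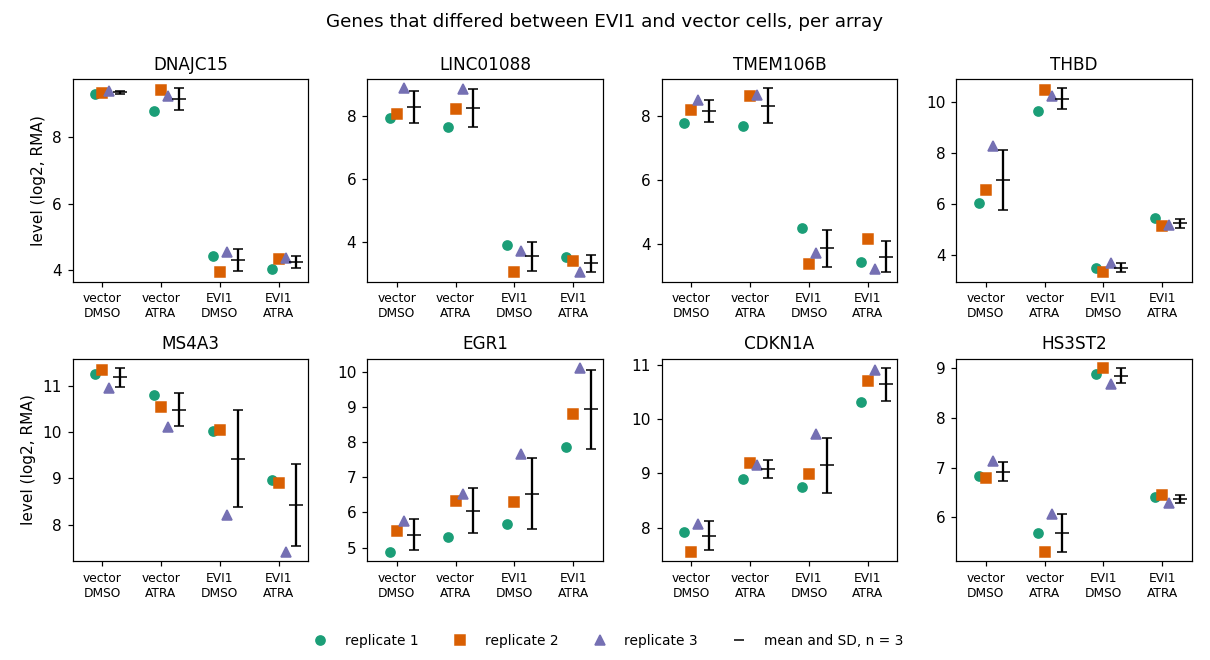
Levels (log2 RMA value, vertical axis) of 8 genes in the 4 groups (horizontal axis); points are arrays, with a colour and shape for each replicate number, and bars are the mean and SD (n = 3). DNAJC15 fell from 9.35 in vector cells to 4.30 in EVI1 cells under DMSO, while EGR1 was higher in EVI1 cells under ATRA (8.93 against 6.04).

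Without ATRA, camera at the preset correlation called antigen presentation and interferon lists higher in EVI1 cells, though few of their genes passed the test. The MHC class II genes HLA-DRA (1.87; adjusted p = 0.0545, blocked 0.000837), CD74 (1.69; 0.0797, blocked 0.000165) and HLA-DMB (0.53; 0.0519, blocked 0.00262) missed the threshold and passed it with the block. With the median of its probe sets in place of the brightest, CD74 was -0.17 under DMSO (adjusted p = 0.907). Similar sequences of HLA genes make it uncertain which of them a probe set reads. Of 11 MHC class II genes limma called 0 over all genes, while 6 rose adjusted over the list alone, 6 were at an unadjusted p under 0.05 and 7 rose with the block (camera adjusted p = 4.84e-05). All 14 MHC class I genes had positive differences; the peptide transporter TAP1 rose by 0.55, and 5 rose adjusted over the list alone and 6 with the block (camera adjusted p = 3.56e-06). Both lists had adjusted p = 0.555 with an estimated correlation. Of 33 interferon-stimulated genes 28 were positive and HERC5 rose (0.44), with 2 up adjusted over the list alone and 11 with the block (camera adjusted p = 8.8e-06; adjusted p = 0.979 with an estimated correlation). The fry adjusted p was 0.138 for MHC class II, 0.137 for MHC class I and 0.719 for interferon-stimulated genes. Of 15 cell cycle arrest genes CDKN1A and MXD1 (0.64), a MYC antagonist, rose, and 3 adjusted over the list alone and with the block (camera adjusted p = 0.0039; adjusted p = 0.876 with an estimated correlation). With the block, cholesterol synthesis (camera adjusted p = 0.209, blocked 0.0275) and ribosome biogenesis (0.131, blocked 0.044) were called lower in EVI1 cells, and both had an adjusted p of 0.935 with the block and an estimated correlation.

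Under ATRA, the transcription factors EGR3 and EGR1 were higher in EVI1 than in vector cells. EGR3 rose from 4.16 ± 0.32 to 8.64 ± 2.07 (SD, n = 3) and EGR1 from 6.04 ± 0.64 to 8.93 ± 1.13. EMP1 (3.65), the nucleotide receptor P2RY13 (2.95) and the orphan receptor GPR82 (2.69) were the other large rises. In vector ATRA, EMP1 (3.78), EGR3 and P2RY13 (3.98 to 4.93) were near the lower quartile of the arrays, so the sizes of these rises are limited by background. Some of these differences were also present under DMSO. At numbers 1, 2 and 3, EGR1 read 5.66, 6.30 and 7.65 in EVI1 DMSO against 4.88, 5.46 and 5.75 in vector DMSO. EMP1 read 6.01, 6.71 and 7.92 against 4.33, 4.98 and 3.86. EGR3 (7.45), P2RY13 (4.78) and GPR82 (7.31) were clearly above vector DMSO only on EVI1 DMSO array 3. THBD, which ATRA raised in vector cells, was 5.25 ± 0.17 in EVI1 cells against 10.12 ± 0.41 in vector cells, and LINC01088 (-4.92), DNAJC15 (-4.90), TMEM106B (-4.74) and the adhesion molecule CADM1 (-2.65 ± 0.21) were the other large falls. In EVI1 cells THBD also read higher with ATRA (5.45, 5.13 and 5.17) than with DMSO (3.51, 3.34 and 3.71). Those DMSO values lie below the lower quartile of the arrays, so the size of that difference is limited by background. Under ATRA 790 genes passed the limma test, 462 higher and 328 lower in EVI1 cells, against 2954 at an unadjusted p under 0.05, and 169 of them differed by at least 2-fold (109 higher, 60 lower). With the block 3559 passed (1824 higher, 1735 lower), among them all 790 in the same direction. The adjusted p was 0.0241 for EGR3 (4.47 ± 1.00), 0.0153 for EGR1 (2.88 ± 0.58), 0.0101 for EMP1, 0.0164 for P2RY13, 0.0477 for GPR82, 0.000119 for THBD (-4.87 ± 0.43), 1.44e-05 for LINC01088, 8.1e-08 for DNAJC15, 3.22e-05 for TMEM106B and 6.16e-05 for CADM1. All 10 genes moved in the same direction at all 3 replicate numbers, which the naming rule's demand for arrays without overlap fixes in advance.

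Among the genes named in every comparison, MYC (-0.86 ± 0.18; adjusted p = 0.0203) and MS4A3 (-2.05 ± 0.48; 0.0306) were lower and RARA (0.72 ± 0.16; 0.0221) was higher in EVI1 cells under ATRA. RARB (1.16 ± 0.34; 0.07, blocked 0.00182), TGM2 (1.89 ± 0.74; 0.163, blocked 0.00826) and CEBPE (0.72 ± 0.25; 0.115, blocked 0.033) passed only with the block. CYP26A1 (1.36), DHRS3 (0.66), ITGAX (0.46), ITGAM (0.40), CD38 (0.24), GATA2 (-0.11) and CYBB (-0.42) passed neither fit. The probe sets of ITGAM, RARA, GATA2, S1PR3 and DOCK9 other than the one used include at least 1 with the opposite sign, which was not called. The EVI1 effect was largely shared between the agents: 66 genes, such as CDKN1A, were called higher and 91, such as DNAJC15, lower under both, where 2.46 and 2.24 were expected, and none in opposite directions (Fisher's exact p = 9.87e-90 and 1.97e-147, over genes that are not independent replicates; 454 and 339 with the block). Across genes, which are not independent replicates, the EVI1 effects under DMSO and ATRA correlated with r = 0.723 and rho = 0.585. A fixed difference between the cultures other than EVI1 would also be shared between the agents. The labels do not mark independently transduced cultures, so this overlap cannot tell such a difference from EVI1.

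Under ATRA, camera at the preset correlation called proliferation lists lower and antigen presentation lists higher in EVI1 than in vector cells. All 36 cell cycle genes were negative and 3 fell, PCNA (-0.66), MCM4 (-0.77) and CCND2 (-0.58), with 9 down adjusted over the list alone and 25 with the block (camera adjusted p = 3.79e-10). Of 17 ribosome biogenesis genes 4 fell, MYC, CAD (-0.83), RRS1 (-0.80) and POLR1B (-0.61), with 11 down adjusted over the list alone and 13 with the block (camera adjusted p = 1.56e-06). Of 14 primary granule genes the protease gene CTSG (-0.89) and MS4A3 fell, with 5 down adjusted over the list alone and with the block (camera adjusted p = 0.00922). Of 11 MHC class II genes HLA-DRA (1.81), CD74 (1.65), HLA-DMA (1.62) and HLA-DMB (0.64) rose, 7 adjusted over the list alone and 8 with the block (camera adjusted p = 0.000557); with the median of its probe sets in place of the brightest, CD74 was -0.10 (adjusted p = 0.775). Of 14 MHC class I genes TAP1 (0.57) and NLRC5 (0.55) rose, 3 adjusted over the list alone and 6 with the block (camera adjusted p = 0.00497). Each of these 5 lists had adjusted p = 0.488 with an estimated correlation.

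Interferon, arrest and apoptosis lists were also called higher in EVI1 cells under ATRA at the preset correlation. Of 33 interferon-stimulated genes XAF1 (1.22), IRF9 (1.12) and IFI35 (0.68) rose, with 13 up adjusted over the list alone and 20 up and 1 down with the block (camera adjusted p = 7.12e-07). Of 15 arrest genes CDKN1A (1.56), GADD45A (0.78) and MXD1 (0.76) rose, 5 adjusted over the list alone and 7 with the block (camera adjusted p = 0.000932). Of 24 apoptosis genes BCL2A1 (2.09), TNFRSF10B (0.60) and BAK1 (0.43) rose and CASP1 (-0.72) fell, with 9 up and 3 down adjusted over the list alone and 13 up and 3 down with the block (camera adjusted p = 0.000588). Each of these 3 lists had adjusted p = 0.488 with an estimated correlation. With the block, lysosome genes (camera adjusted p = 0.0604, blocked 0.0312) and lipid mediators (0.0911, blocked 0.0489) were called higher and cholesterol synthesis lower (0.124, blocked 0.0169). With the block and an estimated correlation the adjusted p was 0.567 for lysosome genes, 0.491 for lipid mediators and 0.567 for cholesterol synthesis.

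The other fixed lists were called in no comparison without the block. Their smallest camera adjusted p over the 5 comparisons was 0.0742 for retinoid genes, 0.112 for haematopoietic transcription factors, 0.0756 for cytokines, 0.124 for cholesterol synthesis, 0.131 for cholesterol efflux, 0.0718 for glycolysis, 0.0591 for unfolded protein stress and 0.063 for genes linked to EVI1. Transcription factors went both ways in vector cells, where KLF4 fell (-1.54), LMO2 fell (-0.62) and ID1 rose (2.07). Camera tests for a shift in 1 direction, so it can miss lists whose members go both ways. At an unadjusted limma p under 0.05, 5 of 15 genes linked to EVI1 were higher and 3 lower in EVI1 cells under ATRA. Under DMSO 2 were higher and 3 lower. For the interaction 3 were more positive and 2 more negative, and 3 and 3 of 29 transcription factors. Over all 14080 genes the counts were 2954, 1379 and 362. Median, mean and test differed in sign in 24 of the 145 combinations of list and comparison, of which 0 were called. These were, for ATRA in vector cells, transcription factors, cytokines and B cell markers. For ATRA in EVI1 cells they were glycolysis and the megakaryocyte, B cell and epithelial markers. For EVI1 against vector under DMSO they were retinoid, monocyte, granulocytic, NADPH oxidase, cholesterol efflux, glycolysis, unfolded protein and EVI1-linked genes and the T and NK and fibroblast and endothelial markers, and under ATRA glycolysis, unfolded protein and megakaryocyte genes. For the interaction they were MHC class II and unfolded protein genes and the erythroid and B cell markers. Markers of other cell types were not called as lists, with smallest adjusted p of 0.516 for erythroid, 0.563 for megakaryocyte, 0.423 for T and NK, 0.407 for B cell, 0.525 for epithelial and 0.0612 for fibroblast and endothelial genes. Single members moved: CD79B rose with ATRA in EVI1 cells (0.55) and was higher than in vector cells under ATRA (0.77), as were FBN1 (1.41 and 0.92) and PECAM1 (1.10 and 1.00).

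Counts of called genes depended on single arrays. In vector cells the ATRA count was 71 without vector DMSO array 1, 102 without vector DMSO array 2, and 215, 79 and 127 without vector ATRA arrays 1, 2 and 3. In EVI1 cells it was 897 without EVI1 ATRA array 3, 3224 without array 1, 1146 without array 2, and 1042 and 1067 without EVI1 DMSO arrays 1 and 2. For EVI1 against vector under DMSO it was 113, 77 and 95 without vector DMSO arrays 1, 2 and 3, and 87 and 79 without EVI1 DMSO arrays 2 and 3. Under ATRA it was 263 without EVI1 ATRA array 3, 1962 without array 1 and 343 without array 2, and 402, 380 and 287 without vector ATRA arrays 1, 2 and 3.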

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

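The 3 tests of technical explanations in this part were chosen after the larger ATRA response had been seen, while the splits of the samples were chosen before. Each result here stands out because it passed a test of the difference in ATRA effect between EVI1 and vector cells in some settings, though not in others. Cell cycle genes such as MCM4 and PCNA had a median interaction of -0.375, and ribosome biogenesis and MYC target genes, among them MYC and CAD, had a median of -0.37. Apoptosis genes such as BCL2A1 had a median of 0.148 and granulocytic genes such as CEBPE a median of 0.17. These 4 lists passed camera at the preset correlation (adjusted p from 3.16e-10 to 0.0297) and none passed with an estimated correlation (adjusted p of 0.469 each), so they depend on how far genes of a list vary together between arrays. The size of the ATRA response differed by 0.156 with the replicate block (limma roast p of 0.0332) and by 0.193 without it (p of 0.188). With the block the genes lower under ATRA passed on their own (p of 0.0293) and the higher genes did not (p of 0.145).

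The tables argue against 1 technical explanation of the larger ATRA response in EVI1 cells and leave 2 others open. Cyclic loess, which removes trends of signal with level between arrays, left the difference at 0.151 with the block (limma roast p of 0.0369), which argues against such a trend as the whole cause. The ATRA shift in the 3′ to 5′ difference of GAPDH differed between the cell types by 0.0367 (95% interval -0.0698 to 0.143) and that of ACTB by 0.0433 (-0.264 to 0.351). Arrays of a group ranged over up to 0.1 and 0.29, so these measures are too variable to decide on RNA quality. Without EVI1 ATRA array 3 the difference was 0.121, and without vector DMSO array 3 it was 0.122, so a part of the size may rest on either array. With the block and without EVI1 ATRA array 3 it was 0.124 (limma roast p of 0.0733). The difference was largest at number 3 (0.268), where the ATRA effect was smallest in vector cells (0.423) and that in EVI1 cells (0.691) was below that of number 2 (0.731). An effect of EVI1 on the response stays open as a hypothesis and was not separated from other differences between the cultures.

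Other splits of the arrays were compared with the real one. For the size of the response, 59 of the 200 splits of the cell-type labels within each agent gave a value as far from 0 (real value 0.193, highest other 0.437), and 10 of 32 did when labels were exchanged only within replicate numbers. Exchanging labels within 1 agent turns the EVI1 effect itself into a difference in size, and 17 of the 37 other splits that keep the labels of 1 agent were as far from 0. These splits therefore say nothing about chance for the size, and the exact permutation of signs over the 3 replicate numbers cannot go below 0.25. For the EVI1 effect along the ATRA response, 12 of 200 splits were as far from 0 (real value 0.167, highest other 0.218), which is not under 0.05 either, and 1 of 32 within replicate numbers, which is the real split alone. For the interaction, all 100 splits drawn called as many genes as the real one, which called 0, and the highest other called 570. Because the real count is 0, this test says nothing about chance. Exchanging labels within 1 agent turns the EVI1 effect, which includes DNAJC15 and LINC01088, into an apparent interaction, so the high counts point to a structure of the samples.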

How the results depend on the processing

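The alternatives added after the data were seen were leaving out all 4 arrays of a replicate number, the replicate block without EVI1 ATRA array 3 or with cyclic loess, and the block for the overlap of called genes. Counts are given in the order ATRA in vector cells, ATRA in EVI1 cells, EVI1 under DMSO and EVI1 under ATRA, with 496, 2127, 171 and 790 as reported. Cyclic loess, centring, eBayes with trend and robust options, every probe set on its own, the median of probe sets, and no or a stricter signal limit kept all of the 7 results they were run on within 1.5 times or on the same side of the threshold. The majority direction of called genes turned in some. Centring gave 258 higher and 274 lower for ATRA in vector cells, and 396 higher and 419 lower for EVI1 under ATRA. Cyclic loess gave 1259 higher and 1085 lower for ATRA in EVI1 cells. The other 4 MECOM probe sets gave the same call as the brightest.

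The numbers pair the arrays, and the replicate block gave 2818, 5023, 1013 and 3559 genes, a response size difference of 0.156 (limma roast p of 0.0332) and an overlap of 2341 genes. The median residual SD was 0.121 with the block and 0.182 without it, which leaves room for more calls. With the block and without EVI1 ATRA array 3 the counts were 3074, 3898, 1114 and 1984. With the block and cyclic loess they were 2944, 5083, 1095 and 3780, with a size difference of 0.151. Among named genes the block added 126 calls and changed no other call, and among lists it added 11 and lost none of 145.

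Array weights gave 1387, 3888, 382 and 2761, and 1 interaction gene (DDC). Using only the arrays compared lowers the residual degrees of freedom from 8 to 4. It gave 735 for ATRA in EVI1 cells, 92 for EVI1 under DMSO and 269 under ATRA, but more genes, 628, for ATRA in vector cells. Leaving out number 1 gave 147 in vector cells, 93 and 1322 for EVI1, and a size difference of 0.268 (limma roast p of 0.041). Leaving out number 2 gave 0, 5, 12 and 15, with 1118 genes at an unadjusted p under 0.05 behind the 0 in limma, and an EVI1 effect along the ATRA response of 0.171 (p of 0.114). The 5 genes, named after their values were seen, were FABP6 (1.77), HS3ST2, METRNL (-1.62), NOG and PTX3. Leaving out number 3 gave 273, 679, 23 and 71. At 2-fold or more in each cell type the overlap was 130 genes, and with such genes alone the EVI1 effect along the response was 0.360 (p of 0.152, with 317 genes; 0.385 with the block, p of 0.0115). Apart from array weights, which keep all arrays and genes, fewer arrays or genes enter these settings; beyond that the cause was not tested.

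Without 1 array at a time the counts ranged over 71 to 402, 897 to 3224, 77 to 130 and 263 to 1962, and the interaction over 0 to 1. The size difference ranged from 0.121 to 0.325 (p of 0.0393 to 0.446) and the effect along the response from 0.129 to 0.232 (p of 0.0086 to 0.134). Leaving out 1 array unbalances the groups, so for the last pair of results the choice of genes is then not independent of the value. CD74 under ATRA reversed with the median of its probe sets (-0.10, adjusted p of 0.775), and under DMSO, where it was not called, it went from 1.69 to -0.17 (0.907); the cause was not tested.

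An estimated correlation ended all 37 camera calls it was run on, and fry lost 22 and added 5. Without the signal limit lists lost 1 call and gained 5. Over named genes, leaving out 1 array lost 524 and added 51, cyclic loess lost 13 and added 4, and the median of probe sets lost 36 and added 13. Signal over background limits genes near the lower quartile (3.83 to 3.91), such as MECOM, CD14 and DNAJC15 in EVI1 cells, whose absence cannot be told from low expression on these arrays.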

Other observations

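ATRA moved single genes of metabolism and regulation as well, which are named here after their values were seen. The transcription factor KLF4 fell in vector cells (-1.54 ± 0.15, SE, n = 3) and in EVI1 cells (-1.60 ± 0.15), and ID1, an inhibitor of differentiation factors, rose in both (2.07 and 3.14). DDIT4, which restrains growth signalling, rose in both (2.09 and 2.31), and the hexokinase gene HK2 fell in both (-0.87 and -1.16). The growth factor VEGFA fell in both (-0.86 and -0.93). In EVI1 cells ATRA also raised the oxysterol receptor NR1H3 (1.66), the glucose transporter SLC2A1 (1.08), the glycolytic regulators PFKFB3 (1.0) and PFKFB4 (0.99), and the chemokine CCL24 (2.09), and lowered the serine synthesis enzyme PSAT1 (-1.57), the stress regulator ATF4 (-0.85), and the haematopoietic factors ERG (-1.32) and MYB (-0.76). The neutrophil calprotectin genes S100A8 (3.06, limma adjusted p of 0.00859) and S100A9 (3.49, 0.0166) rose with ATRA in EVI1 cells and were called in vector cells only with the replicate block (1.82, adjusted p of 0.149, blocked 0.0371, and 2.38, 0.153, blocked 0.025). Their interaction was not called (adjusted p of 0.998).

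CASP1, ALDH1A1 and CD9 were lower in EVI1 cells under both agents, and these genes were again chosen after their values were seen. CASP1, which encodes the protease that matures interleukin 1, was lower by -0.85 under DMSO and -0.72 under ATRA, though ATRA raised it in both cell types (0.47 and 0.59). The retinaldehyde dehydrogenase ALDH1A1 was lower by -0.69 and -0.78 and the tetraspanin CD9 by -1.04 and -1.13. CD74 averaged 6.47 in vector DMSO, 6.56 in vector ATRA, 8.16 in EVI1 DMSO and 8.22 in EVI1 ATRA, and HLA-DRA 8.61, 8.44, 10.49 and 10.25. Under DMSO these 2 were called only with the block (CD74 limma adjusted p of 0.0797, blocked 0.000165; HLA-DRA 0.0545, blocked 0.000837). The CD74 levels are those of its brightest probe set, and with the median of its probe sets the difference was -0.17 under DMSO (adjusted p of 0.907) and -0.10 under ATRA (0.775). Of 11 MHC class II genes, the 8 on chromosome 6 had a median of 0.99 under DMSO and 0.72 under ATRA, and the other 3 had 0.13 and 0.42. The 9 MHC class I genes on chromosome 6 had 0.28 and 0.24, and the 5 elsewhere 0.22 and 0.12.

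Of the tests in the remaining paragraphs, those on the 4 genes near ASH2L, on the other 23 genes and on their parts of 3 and 20 genes, on windows along chromosomes, on single probe sets and on the cultures were chosen after the result was seen. Large falls in EVI1 cells were found under both agents in 27 genes, among them DNAJC15, LINC01088, TMEM106B, THBD and ASH2L, while 12 genes, among them CDKN1A and DOCK9, were at least 2-fold higher under both. A fault of single probe sets is argued against for 10 of the 27 genes, since 16 of 16 of their other probe sets were also lower, a share of 1. The rest of the 27 had no other probe set above the signal limit, so for them such a fault stays open. Loss of chromosome stretches that reach neighbouring genes was examined with the nearest 5 tested genes on each side. As 1 cause for all 27 genes it is argued against by their 248 neighbours, whose median EVI1 effect was -0.0317. For the 23 genes other than ASH2L, STAR, DDHD2 and TM2D2 as a set, a median of -0.0183 argues against it. These medians cannot detect a loss of only 1 gene or a few genes, which stays open. For 20 of the 23 genes the median was -0.0108, and the lowest median around any 1 of them was -0.15. For THBD (-0.22), NFE2L3 (-0.22) and PLAG1 (-0.25) the neighbours lay lower, with a joint median of -0.219 between the bounds of -0.2 and -0.5. Loss of a stretch that reaches the neighbours stays open for these 3. A difference between the cultures other than EVI1 cannot be told apart from EVI1 for any of the 27 genes, because the labels do not mark independently transduced cultures.

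For ASH2L, STAR, DDHD2 and TM2D2, neighbours on chromosome 8, the surrounding genes were lower as well. Outside the pattern 17 of 18 neighbours were lower, with a median of -0.639, and 8 were called lower under DMSO and 9 under ATRA, among them LSM1, BAG4, NSD3 and TACC1, while FGFR1 (-0.05) was near 0. A candidate explanation is a lower copy number or silencing of this stretch in the EVI1 culture, which these arrays do not separate. The stretch held the lowest median (-0.88) of 13813 windows of 11 genes. The next lowest separate windows were on chromosome 20 (-0.64, -0.56 and -0.52), where THBD also lies, and on chromosome 5 (-0.62), around PRRC1. Across the genome 14 separate windows had a median beyond 0.5 in either direction, against at most 1 in 100 shuffles of the genes and 3 for the ATRA effect, so neighbouring genes differed together more than shuffled genes did. The 5 highest windows were all on chromosome 7, the top one (0.765) around NAMPT (0.77 under DMSO and 1.03 under ATRA) and the next around CDK6 (0.57 and 0.55) with the interferon-induced SAMD9L (1.03 and 1.20). The window of rank 3 (0.733) held FAM200A, which was at least 2-fold higher under both agents. Over the 12 genes with such rises, neighbour medians ranged from -0.38 (RALGAPA2, on chromosome 20) to 0.57 (FAM200A).

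The EGR1 and EGR3 rises in EVI1 cells under ATRA raised the question of a general immediate early response, as handling stress of those cultures could give. EGR1 was also higher in EVI1 than in vector cells under DMSO at every replicate number, and EGR3 on EVI1 DMSO array 3 (7.45). Over 8 immediate early genes outside the fixed lists the median difference was 0.45, between the bounds set beforehand for such a response (above 0.5) and against it (below 0.2), so the test leaves the question open. ZFP36 was higher by 1.11 (limma adjusted p of 0.0119) and was the only one of the 8 called. KLF10 (0.86), JUNB (0.72) and DUSP1 (0.50) were not called, and NR4A1 (0.08) and CCN1 (0.03) were near 0. An effect of EVI1 on these genes was not tested apart from this.

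With 3 arrays against 3, 10 splits exist, so no share under 0.05 can be reached for the counts of called genes. In each of the 4 comparisons of groups the real split alone, 1 of 10, gave as many genes. The real counts were 496 for ATRA in vector cells, 2127 for ATRA in EVI1 cells, 171 for EVI1 under DMSO and 790 under ATRA, where genes such as CD36, PTGES and DNAJC15 were called, and the highest count of the other splits was 0 in each.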
